A study of Mus musculus with 2 samples.

How the data were processed

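The samples were 2 pools of mouse embryonic midbrain, profiled by chromatin immunoprecipitation and sequencing with an antibody against H3K4me1. Per the labels, replicate 1 pooled 24 embryos and replicate 2 pooled 34, at embryonic day 14.5 and with both sexes in each pool, and both belong to 1 group. The labels number them as biological replicates, so the spread between them includes that between separate pools of tissue. It also includes any difference between the libraries in depth or peak calling, which is unknown here.

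The authors deposited 4 peak lists in narrowPeak format on mm10, per the notes deposited with the lists: 1 for each replicate alone, 1 called on both replicates together, and 1 of replicated peaks derived from the other 3. Per the same notes, the list of replicate 1 and the pooled list name 1 more parent file than that of replicate 2, and what that file holds is not said. Per the labels, a control experiment is named as possible, and which lists used it is not said. The aligner, the peak caller, the filters on reads and the calling threshold are not given in the sources used here. Each list gives the authors' signal per peak, a deposited signal value whose scale no header states, and it was used only to rank and describe peaks within a list. Deposited alongside it are −log10 p and −log10 q per peak. The deposited score column holds a display score and was read but not used for any result. The lowest −log10 p was 2.00 in replicate 1 and 2.09 in replicate 2, so the lists include weak calls, and 73.3% and 81.7% of their peaks had a −log10 q of at least 2. A peak caller's threshold sets how many peaks a library yields, and a library of greater depth yields more, so counts of peaks are not levels of the mark. The reads were not used here and the depth of each library is unknown.

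Replicate 1 had 2 peaks on sequences outside the assembled chromosomes, which were left out of overlaps and locations. Coordinates are 1-based on mm10. The reference was the GRCm38 assembly, which has the same chromosomes as mm10, with GENCODE gene models of the same assembly. All 20 chromosomes that the lists name were in it, and 0 peaks ran past a chromosome's end. A gene's start site is the 5′ end of its gene record, taken for 21911 protein-coding genes.

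Peaks were located by their midpoint, in the order promoter (within 1 kb of a start site), exon, intron and intergenic, and each share was divided by the share of the genome in that class. Peaks counted as shared where the overlap was at least 50% of either peak, and chance overlap came from 100 circular shifts along each chromosome. Start sites were CpG-rich where the 500 bp on either side had a ratio of observed to expected CpG of at least 0.6 and a GC content of at least 50%, and profiles ran to 5 kb on either side in steps of 100 bp. The strength of a gene's surroundings was the share of bases under peaks within 50 kb of its start site. The lists of genes were fixed before the data were examined: midbrain patterning, dopaminergic, GABAergic and glutamatergic lineages, serotonergic and isthmic hindbrain, neural progenitor, pan-neuronal, oligodendrocyte, forebrain, Hox clusters, endothelial, pericyte, microglia, erythroid, mesenchyme, liver, muscle, epidermis, lymphoid, germline, housekeeping, olfactory receptors, vomeronasal receptors and all Hox genes. Ahsp and Ighm were not found among the protein-coding genes of the annotation. A list's median was placed among 10000 random lists of its size drawn from the other genes, matched on quintiles of the number of start sites in the window. Genes and peaks are not replicates, so no p-value was computed across them. With 1 group there was no contrast and no test between groups.

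The named genes followed a rule fixed with the lists: the 3 highest and the lowest member of each list, the 10 widest and the 10 highest-signal replicated peaks, the 10 genes with the highest covered share, where a gene whose start site lies within 50 kb of one already named is given with it and not counted, and the 5 highest-signal peaks found in each replicate alone. Where several members tied for lowest, 1 or more of them are named.

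The placement of lists was tested on simulated data before use. Among 21911 genes with 200 raised by a known factor, 100 lists of 14 genes were drawn for each factor. Of lists without a planted change 5 of 100 fell outside the central 95%. Above it lay 40 with a planted rise of 1.5 times, 66 with 2 times and 95 with 3 times. A list within the central 95% therefore does not exclude a rise of 2 times. Falls and clustered genes were not simulated, so the simulation sets no limit on them. Alternatives covered a minimum −log10 q of 2, the top 25% of each list, other overlaps, other promoter widths and annotations, windows of 10 and 100 kb, other matching, the pooled list and each replicate alone. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, and samtools 1.23.1.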

Results

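Monomethylation of histone H3 at lysine 4 (H3K4me1), a chromatin mark known from enhancers and from the flanks of active promoters, was mapped by chromatin immunoprecipitation and sequencing in the midbrain of mouse embryos at embryonic day 14.5. There was 1 group with 2 biological replicates. Replicate 1 came from the pooled midbrains of 24 embryos and replicate 2 from those of 34, and both pools held males and females. With 1 tissue, 1 stage and no second condition, the design asks where the mark lies in this tissue and how alike the replicates are. The data were 4 lists of called peaks on the mm10 build, namely 1 list per replicate, a pooled list called on both replicates together, and a replicated list drawn from the other lists. The lists give no read totals, so the depth of each library is unknown here and no interval that needs it is given. All values marked ± are the mean and SD over the 2 replicates (n = 2), and the signal and −log10 p of a peak are the authors' own values.

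H3K4me1 covered a small part of the genome in many narrow peaks. Replicate 1 had 147658 peaks over 66.9 Mb and replicate 2 had 121536 peaks over 56.0 Mb, a mean of 134597 ± 18471 peaks and 2.25% ± 0.28 of the genome. The replicated list held 78824 peaks over 61.7 Mb, or 2.26% of the genome. Its peaks were wider, with a median of 599 bp against 322 bp in replicate 1 and 338 bp in replicate 2, and 3413 of them were over 2 kb wide. The median −log10 p was 5.27 in replicate 1, 5.39 in replicate 2 and 7.56 in the replicated list.

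Most of the peaks lay away from start sites, inside introns and between genes, while promoters held far more of them than their length would give. In the replicated list 52.5% of the peaks had their midpoint in an intron, 30.5% lay between genes, 11.6% lay in a promoter (within 1 kb of the start site of a protein-coding gene) and 5.37% in an exon. Promoters make up 1.52% of the genome, so the share of promoter peaks was 7.66 times that of the genome in the replicated list and 6.13 ± 0.25 times in the replicates' own lists. The same ratio was 1.69 for exons, 1.54 for introns and 0.499 for intergenic sequence. The median distance from a replicated peak to the nearest protein-coding start site was 32170.5 bp, 65.03% of the peaks lay more than 10 kb away and 22.6% lay within 2 kb. The promoter ratio fell to 4.07 when the start sites of all annotated genes were counted.

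At start sites in CpG-rich sequence the mark flanked the start site and was sparse on it. Of 9725 protein-coding genes with a CpG-rich start site, 6.92% had a replicated peak over the start site itself, 51.6% had a peak 1100 bp downstream and 30.1% had a peak 700 bp upstream. In the replicates' own lists these shares were 6.44% ± 0.75, 46.2% ± 3.99 and 27.4% ± 3.72, and both replicates had their maxima at the same positions. At the 12186 CpG-poor start sites there was no such dip, with 10.2% covered at the start site and a maximum of 12.1% downstream. The ratio of the mean of the upstream and downstream maxima to the start site was 5.90 for CpG-rich sites (5.78 ± 1.27 over the replicates). For CpG-poor sites this ratio was 1.099 (1.06 ± 0.01). The ratio rose to 11.8 for CpG-rich sites defined by a stricter ratio of observed to expected CpG of at least 0.75.

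**Figure D1:**
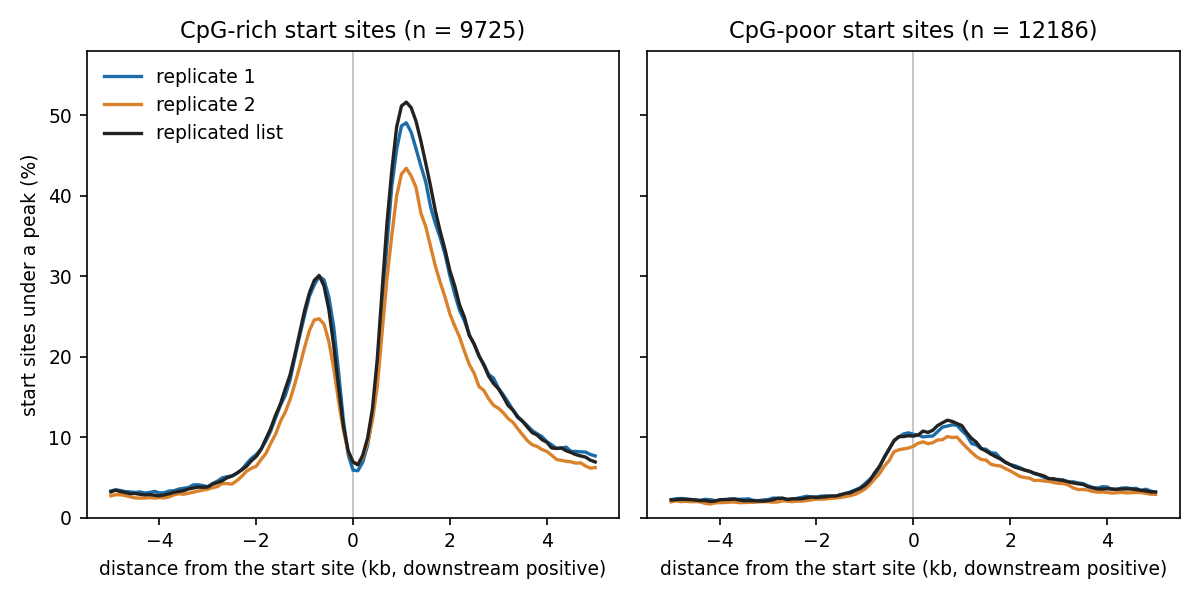
Share of protein-coding start sites under an H3K4me1 peak (%, vertical axis) by distance from the start site (kb, horizontal axis, downstream positive), for CpG-rich sites on the left and CpG-poor sites on the right, with lines for replicate 1, replicate 2 and the replicated list. CpG-rich sites have a dip at the start site (6.92% in the replicated list) between flanks of 30.1% upstream and 51.6% downstream, and CpG-poor sites reach at most 12.1% in the lists drawn.

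Pipox, Flrt1 and Tcf20 had the largest shares of H3K4me1-covered bases around their start sites. For each of 21911 protein-coding genes, the share of bases under replicated peaks was measured within 50 kb of the start site. The median gene had 2.53%, 22.5% of genes had no peak, and the highest 10% of genes began at 9.99%. The highest value, 54.9% (49.8% ± 0.37), belonged to Pipox, a peroxisomal oxidase gene on chromosome 11 at 77880615 to 77894096. Its window is shared with Sez6, a neuronal membrane protein gene at 77930800 to 77979048, which had 41.1% (37.5% ± 1.57). Flrt1, which encodes an adhesion protein with leucine-rich repeats (chromosome 19, 7092001 to 7105729), had 51.8% (46.1% ± 1.43). Tcf20, a transcriptional coregulator gene on chromosome 15 (82808436 to 82987872), had 46.2% (42.5% ± 2.73). Ncor2, the nuclear receptor co-repressor gene on chromosome 5 (125017153 to 125179219), had 42.0% (37.6% ± 1.92), and Zmiz1 on chromosome 14 (25459185 to 25666743) had 41.9% (38.1% ± 0.37). With Sez6 counted together with Pipox, the next were Ccdc85c on chromosome 12 (39.1%), Ssbp3 on chromosome 4 (38.6%), which encodes a partner of LIM homeodomain complexes, and Srgap3 on chromosome 6 (36.8%), a GTPase-activating protein gene of the Slit and Robo pathway. Bahcc1 on chromosome 11 (36.7%) and Tle3 on chromosome 9 (36.5%), a Groucho-type co-repressor gene, were the last of the 10 counted in this way.

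**Figure D2:**
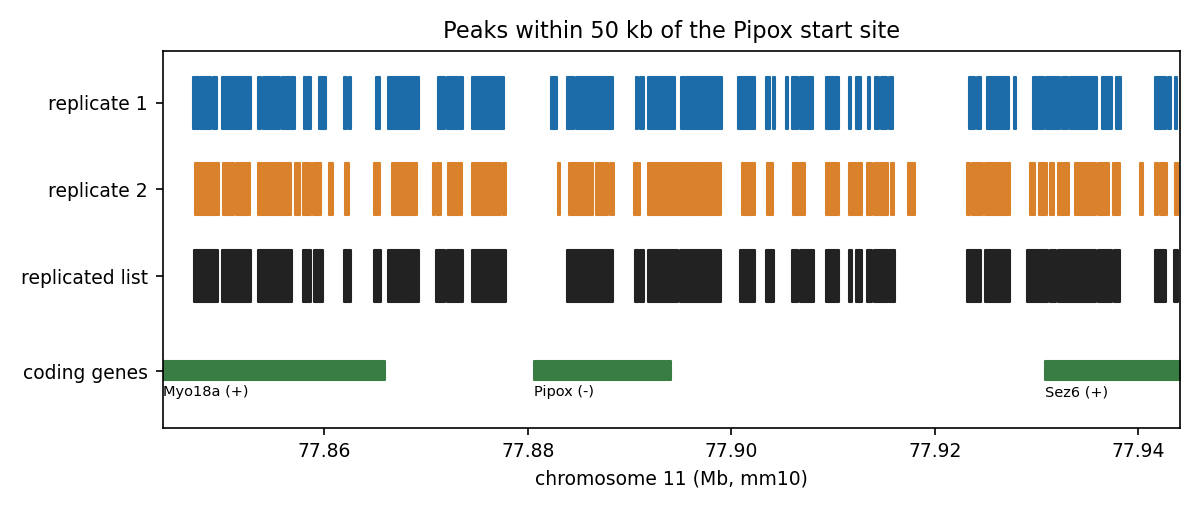
Map of the window within 50 kb of the Pipox start site on chromosome 11 (Mb, mm10, horizontal axis), with the peaks of replicate 1, replicate 2 and the replicated list as blocks and the protein-coding genes Myo18a, Pipox and Sez6 with their strands. Replicated peaks cover 54.9% of the window, and peaks of both replicates lie in the same stretches.

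The 10 widest replicated peaks all lay in introns. The widest replicated peak spanned 11254 bp in an intron of Rara, the retinoic acid receptor alpha gene (chromosome 11, 98960699 to 98971952), with the start site of Gjd3 nearest at 11064 bp. The next was 11151 bp wide (chromosome 1, 132192174 to 132203324) in introns of Lemd1 and of the overlapping gene AC124108.1. Peaks of 10706 bp in Ephb2, an ephrin receptor gene (chromosome 4, 136748688 to 136759393), and of 10660 bp in Ncor2 (chromosome 5, 125150475 to 125161134) followed. Kif21b, a kinesin gene, held a peak of 9978 bp (chromosome 1, 136134237 to 136144214), and Ptprn2 a peak of 9435 bp (chromosome 12, 117194914 to 117204348), 312131 bp from the nearest start site, that of Rapgef5. Zfp423, a zinc finger gene, held 2 of the 10, of 9197 bp (chromosome 8, 87686814 to 87696010; nearest start site 4933402J07Rik, at 122961 bp) and 8752 bp (chromosome 8, 87830129 to 87838880). The others were 9111 bp wide in Klf7 (chromosome 1, 64059755 to 64068865) and 9045 bp wide in Tspan5 (chromosome 3, 138850605 to 138859649). Each of the 10 regions was called as 1 to 7 separate narrower peaks in each replicate's own list.

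The peak with the highest signal, 11.7, lay between genes on chromosome 2 (30646775 to 30648556), 51735 bp from the nearest start site, that of Cstad. A second intergenic peak with Cstad as its nearest start site (chromosome 2, 30691761 to 30693038) was also among the 10 highest, with 9.91. The remaining 8 lay inside genes. Signals were 10.5 in an exon of Tspyl1 (chromosome 10, 34283414 to 34285153), 9.96 in an intron of Ahdc1 (chromosome 4, 133041264 to 133049918) and 9.91 in an intron of Fasn, the fatty acid synthase gene (chromosome 11, 120820732 to 120823335). Introns of Grm4, a metabotropic glutamate receptor gene (chromosome 17, 27500408 to 27504308), and of Mef2d, a MADS-box transcription factor gene (chromosome 3, 88148425 to 88153853), held peaks of 9.91 each. Peaks in introns of Iffo1 (chromosome 6, 125145830 to 125148194), Tcf20 (chromosome 15, 82924740 to 82931387) and Phactr3 (chromosome 2, 178302732 to 178305482; nearest start site Sycp2, at 102203 bp) had 9.77, 9.60 and 9.49. Both replicates had at least 1 peak in each of these 10 regions, with a highest signal of 7.66 to 10.4 in replicate 1 and 7.60 to 11.5 in replicate 2.

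In the replicated list, within 50 kb of the start site, midbrain patterning, neural progenitor and pan-neuronal genes had the highest medians of the 24 gene lists fixed before the data were examined. Each list's median was set against 10000 random lists of the same size with like numbers of start sites in the window, and a list stood apart outside the central 95% of them. That percentile describes these libraries and is no p-value, since genes are not replicates. By this rule 6 lists stood above, 4 below and 14 within, where chance would put about 1.2 outside if genes and lists were independent. They are not fully so, since all 20 genes of the Hox clusters list are also in the list of all Hox genes, and both stood below. The 14 midbrain patterning genes had a median of 11.2% (10.3% ± 1.42) against 1.71% in random lists (percentile 100). Of these genes 12 lay above the genome's median. The highest were Pou3f3 with 18.7% (16.9% ± 1.86) and the transcription factor genes Pax7 with 17.9% (16.4% ± 1.34) and Barhl1 with 15.95% (14.04% ± 3.21), and the lowest was En1 with 0.805% (3.01% ± 0.53), a gene of the midbrain and hindbrain boundary region. The 18 pan-neuronal genes had a median of 7.82% (7.13% ± 1.65; percentile 100), from 23.2% at Rbfox3, which encodes the nuclear antigen NeuN, 18.8% at the adhesion gene Ncam1 and 16.4% at Myt1 down to 1.52% at Elavl4. The 15 neural progenitor genes had a median of 8.53% (6.595% ± 1.80; percentile 99.99), led by Notch1 with 27.6%, the intermediate filament gene Nes with 19.9% and the Notch target Hes5 with 13.7%, while Sox3 on the X chromosome had no peak. The 10 oligodendrocyte lineage genes had a median of 6.08% (6.35% ± 0.51; percentile 99.6), with Sox8 at 12.6%, Olig1 at 9.91%, the myelin gene Mbp at 8.15% and Plp1, on the X chromosome, without a peak. Within 10 kb of the start site the oligodendrocyte list did not stand apart (percentile 80.1), while within 100 kb its median (6.99%) was above those of the neural progenitor (6.33%) and pan-neuronal lists (5.63%).

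Which lists of single neuron types stood above the random lists depended on the setting. In the main setting the serotonergic and isthmic list stood above and the glutamatergic, GABAergic and dopaminergic lists did not. Within 10 kb of the start site the glutamatergic (percentile 99.7) and GABAergic lists (99.8) stood above and the serotonergic list (91.7) did not. The GABAergic list also stood above in each replicate alone (98.1 and 97.9), and the glutamatergic list within 100 kb (97.7), in the pooled list (98.5) and in replicate 1 alone (99.1). Matched on gene length, the glutamatergic (80.4), GABAergic (70.9) and dopaminergic lists (63.7) lay well inside, as they did with the strongest 25% of peaks (71.9, 72.4 and 24.9). The GABAergic list was at 79.9 when matched on CpG class. The 14 glutamatergic lineage genes had a median of 3.51% (3.85% ± 0.95; percentile 97.2), although Ebf3 reached 29.3%, Ebf1 15.6% and Lhx1 15.6%, with Tfap2d at 0. The 14 GABAergic lineage genes had 3.19% (3.83% ± 0.44; percentile 93.5), with Zfpm1 at 16.8%, the vesicular GABA transporter gene Slc32a1 at 11.95%, the proneural gene Ascl1 at 10.04% and Zfpm2 at 0.968%. The 14 dopaminergic lineage genes had 2.85% (2.997% ± 0.28; percentile 90.2), with Neurog2 at 7.69%, the dopa decarboxylase gene Ddc at 7.23%, Msx1 at 7.14% and Ret at 0.289%. The 10 genes of serotonergic neurons and the isthmic hindbrain had 4.79% (4.81% ± 0.93; percentile 98.5), with Lmx1b at 13.2%, Gata2 at 9.19%, Fev at 9.10% and Tph2, the tryptophan hydroxylase gene of serotonin neurons, at 0.537%. Lmx1b also belongs to the midbrain patterning list and Gata2 to the GABAergic list. The 18 forebrain patterning genes had 2.58% (2.66% ± 0.17; percentile 82.6, but 99.4 within 10 kb and 97.7 by number of peaks), with Lhx2 at 7.97%, Emx1 at 4.95%, Lhx6 at 4.88% and Arx, on the X chromosome, without a peak.

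Among the 24 lists, the Hox and chemosensory receptor lists had the lowest medians in the replicated list. The 20 genes of the Hox clusters list, which pattern the body axis behind the midbrain, had a median of 0.674% (0.80% ± 0.35) against 5.31% in random lists (percentile 0.22). The highest were Hoxa1 and Hoxa2 with 3.07% in a shared stretch and Hoxd3 with 1.78%, and the lowest were Hoxb4 and Hoxb9 with 0.253%. All 39 Hox genes together also had a median of 0.674% (0.73% ± 0.37; percentile 0), with Hoxd8 at 2.09% and Hoxc13 without a peak. Of 1134 olfactory receptor genes 1015 had no peak, and of 328 vomeronasal receptor genes 311 had none. Both medians were 0 in the replicated list and in both replicates (percentile 0). The highest olfactory receptor genes were Olfr221 with 12.8%, Olfr1513 with 7.15% and Olfr90 with 6.91%, and the highest vomeronasal genes were Vmn1r233 with 4.17%, Vmn1r4 with 3.84% and Vmn1r188 with 3.59%. Olfr1 and Vmn1r10 were among those without a peak. Genes of these lists lie in clusters and share windows, so they are fewer independent regions than genes. With members thinned to 100 kb apart, a setting chosen after seeing the data, only 6 genes of each Hox list remained. Their medians were still far below those of random lists, 0.485% against 4.71% for the Hox clusters and 0.291% against 4.26% for all Hox genes, while the percentiles were 3.39 and 3.15. Both receptor lists stayed at 0.

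Marker genes of other cell types that a midbrain dissection could hold did not stand apart in the main setting, and housekeeping genes did. The 14 endothelial genes had a median of 2.22% (2.24% ± 0.31; percentile 55.4), with Eng at 8.99%, Sox18 at 7.24%, Esam at 7.19% and Tek at 0. The 10 pericyte and mural genes had 2.13% (2.18% ± 0.20; percentile 58.7), with Pdgfrb at 7.26%, Tagln at 6.66%, Cspg4 at 5.48% and Rgs5 at 0.718%. The 12 microglia and macrophage genes had 2.20% (2.37% ± 0.13; percentile 38.5), with the complement gene C1qa at 14.4%, Laptm5 at 7.86% and Aif1 at 7.54%, and with Itgam and Mrc1 at 0. The 14 mesenchyme and meninges genes had 2.43% (2.58% ± 0.14; percentile 72.8), with Twist2 at 4.73%, Col1a1 at 4.44%, Foxd1 at 3.87% and 3 genes at 0, Lum among them. The 11 erythroid genes had 0.812% (1.03% ± 0.99) against 4.18% in random lists (percentile 3.07, and 1.42 in replicate 2 alone). They were split between Klf1 with 11.2%, Slc4a1 with 10.3% and Epor with 10.1% and 5 genes without a peak. Among these 5 were the globin genes Hbb-bs and Hbb-bt, and Gata1 and Alas2, which lie on the peak-poor X chromosome. Of lists from other organs, the median was 4.57% for 14 heart and skeletal muscle genes (percentile 92.9; Myh7 10.7%, Myod1 10.3%, Mylpf 10.04%, Tbx5 0.572%), and 0.906% for 12 liver genes (percentile 6.09; Apoa2 11.9%, Tat 4.74%, Hnf1a 4.17%, Serpina1a 0). It was 1.497% for 12 epidermis genes (percentile 20.5; Grhl3 14.3%, Grhl2 4.86%, Krt1 4.14%, Trp63 0), 2.36% for 11 lymphoid genes (percentile 21.4; Cd4 19.4%, Cd79a 6.30%, Rag2 5.67%, Cd8a 0) and 1.38% for 12 germline genes (percentile 20.2; Zp3 5.47%, Stra8 4.17%, Pou5f1 2.30%, Dazl 0). The 18 housekeeping genes had 6.40% (6.19% ± 0.80) against 3.41% in random lists (percentile 98.0), with Vcp at 15.2%, Polr2a at 11.7%, Ywhaz at 9.07% and Hprt, on the X chromosome, at 0.78%.

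When only the strongest 25% of the replicated peaks were kept, midbrain patterning (percentile 99.9) and pan-neuronal genes (99.9) still stood above, while neural progenitor (60.2), oligodendrocyte lineage (50.1), serotonergic and isthmic (91.0) and housekeeping genes (97.0) did not. The medians stayed above those of random lists for housekeeping (3.03% against 1.33%), serotonergic and isthmic (1.37% against 0.342%) and neural progenitor genes (0.579% against 0.324%), and were 0.602% against 0.60% for the oligodendrocyte list. Matched on gene length in place of start site density, the Hox clusters (7.92), all Hox genes (4.58), the oligodendrocyte list (97.3) and the serotonergic list (92.1) no longer stood apart. The random lists then had medians of 2.26% and 2.16% against 0.674% for both Hox lists, 2.56% against 6.08% for the oligodendrocyte list and 2.35% against 4.79% for the serotonergic list. Matched on both start site density and CpG class, a setting chosen after seeing the data, the serotonergic (96.3) and housekeeping lists (94.0) did not stand apart, while the heart and skeletal muscle list stood above (98.4).

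**Figure D3:**
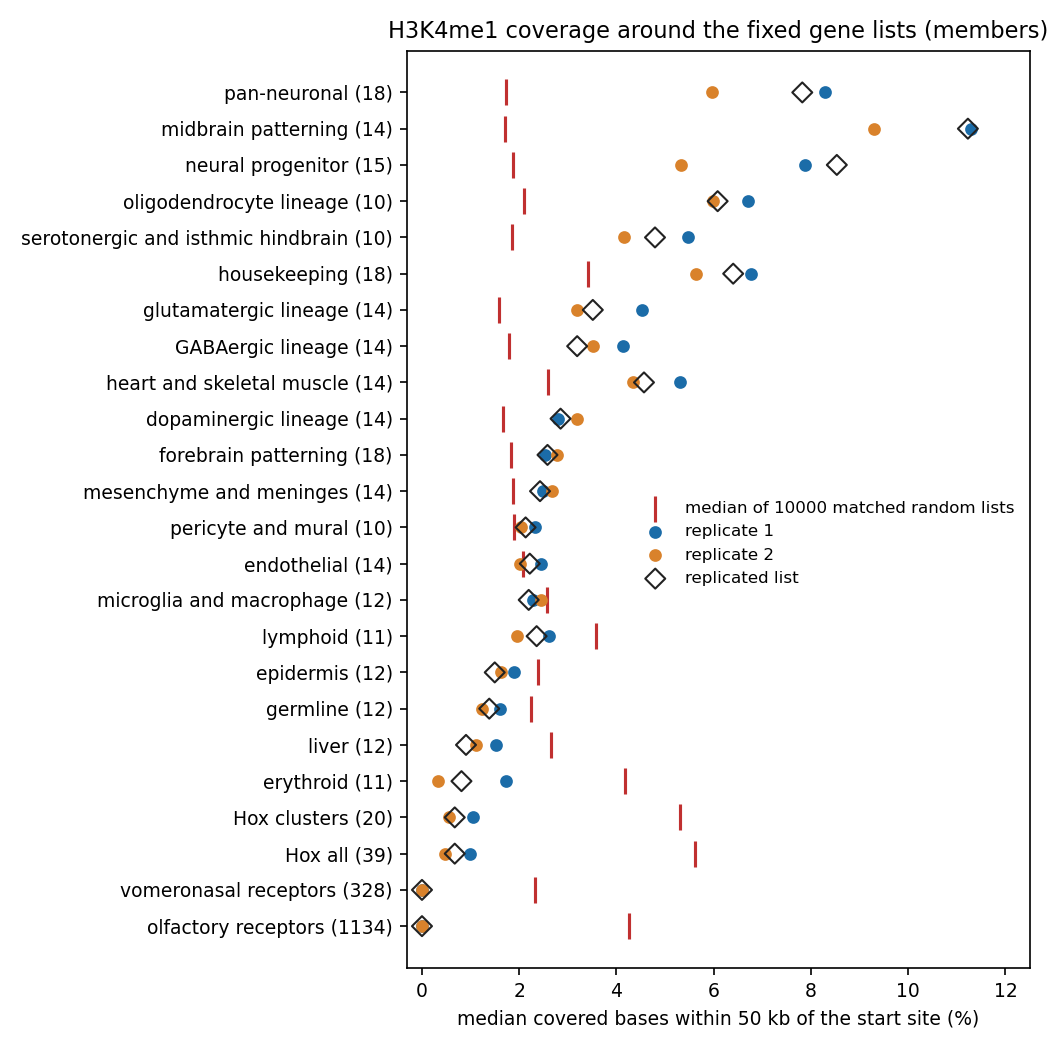
Median share of bases under peaks within 50 kb of the start site (%, horizontal axis) for each of the 24 gene lists (vertical axis, members in brackets, sorted by percentile), with dots for the replicates, diamonds for the replicated list and bars for the median of 10000 matched random lists. Midbrain patterning reaches 11.2% against 1.71%, and the Hox lists lie at 0.674% against 5.31% and 5.61%.

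The X chromosome held far fewer peaks than any autosome. Replicated peaks covered 0.147% of the X chromosome against a median of 2.48% over the 19 autosomes, which ranged from 1.82% on chromosome 14 to 4.01% on chromosome 11, so that the autosomal median was 16.9 times the X value. In the replicates' own lists the X chromosome had 0.214% and 0.169%, or 0.192% ± 0.031, and the ratio was 12.6 and 13.3. The X chromosome makes up 6.28% of the assembled length and carried 448 replicated peaks, 0.568% of all. It has 5.54 protein-coding start sites per Mb, more than chromosome 12 with 5.35, which had 2.48% of its length under peaks. Over the autosomes the covered share went with the density of start sites (Spearman's rho 0.693 across 19 chromosomes, which are not independent replicates). No list held a peak on the Y chromosome, although both pools included males.

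**Figure D4:**
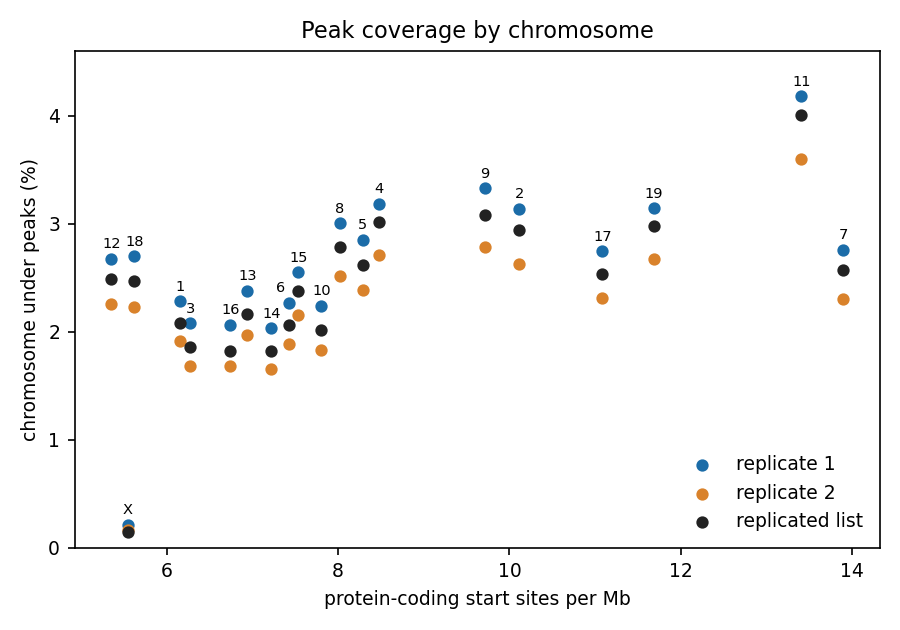
Share of each chromosome under peaks (%, vertical axis) against its protein-coding start sites per Mb (horizontal axis), with dots for replicate 1, replicate 2 and the replicated list and the chromosome's name beside the dot of replicate 1; the Y chromosome, without peaks, is not drawn. The X chromosome lies at 0.147% in the replicated list, and the autosomes lie between 1.82% and 4.01%.

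The replicates shared most of their strong peaks and a minority of their weak ones. Of the peaks of replicate 1, 47.8% overlapped a peak of replicate 2 by at least 50% of the length of either, against 2.90% after shifting the other list along the chromosomes (mean of 100 shifts). For replicate 2 the share was 59.4% against 3.54%. The Jaccard index of covered bases was 0.386 against 0.013 after shifting. Among the strongest 10% of peaks by −log10 p, 93.7% of replicate 1 and 95.9% of replicate 2 were shared, and among the weakest 10% 23.7% and 36.6%. Over 70204 overlapping pairs of peaks, Spearman's rho of the signal was 0.341, across peaks, which are not independent replicates. Summed over windows of 50 kb on either side of the start site, the covered share of genes had a rho of 0.972 between the replicates, across genes. Under the stricter demand of 50% of both peaks, the shared part fell to 29.4% in replicate 1 and 35.7% in replicate 2.

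Peaks found in 1 replicate alone were mostly weak. Replicate 1 had 64931 peaks (43.97%) without a base in common with replicate 2, with a median signal of 2.97 against 3.61 for the others, and replicate 2 had 38401 such peaks (31.6%), with 3.10 against 3.66. The highest of replicate 1 lay in an intron of Fam172a (chromosome 13, 77893522 to 77893984; signal 7.03; nearest start site Pou5f2), in introns of Exoc2 (chromosome 13, 30972726 to 30973135; 6.83), Tial1 (chromosome 7, 128459057 to 128459358; 6.79) and Ric8b (chromosome 10, 84960242 to 84960866; 6.55), and at the promoter of Igsf21 (chromosome 4, 140246961 to 140247693; 6.55). Those of replicate 2 lay in introns of Mkln1 (chromosome 6, 31410100 to 31410520; 6.68), Tsc22d2 (chromosome 3, 58421430 to 58421861; 6.47), Saraf (chromosome 8, 34156736 to 34157080; 6.47) and Ank (chromosome 15, 27488140 to 27488593; 6.42), and in an exon of Lrrc27 (chromosome 7, 139233727 to 139234245; 6.47; nearest start site Pwwp2b). The highest of them ranked 679th by signal in replicate 1 and 1746th in replicate 2.

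Of the 129828 pooled peaks, 78824 were in the replicated list, or 60.7% (95% Wilson interval 60.4% to 61.0%, counting error only). Only 53.6% of the pooled peaks shared at least 1 bp with a peak in each replicate's own list. The replicated list therefore holds some peaks without a counterpart in at least 1 of those lists. By which rule they entered it was not tested. The share of pooled peaks in the replicated list rose from 13.5% in the weakest 10% by −log10 p to 100% in the strongest. Promoter peaks were in it most often, with 71.8%, followed by exon peaks with 66.0%, intron peaks with 60.4% and intergenic peaks with 57.1%. Among pooled peaks of middling strength (bins 4 to 7 of 10) the shares were 68.6% (67.3% to 69.9%), 65.1% (63.2% to 67.001%), 63.9% (63.4% to 64.5%) and 62.8% (62.0% to 63.5%). The interval of promoter peaks was clear of the others and the rest overlapped their neighbours. Strength was not equal within these bins, since the share rose from 41.5% in bin 4 to 86.5% in bin 7. Whether the promoter difference would remain at equal strength was not tested.

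**Figure D5:**
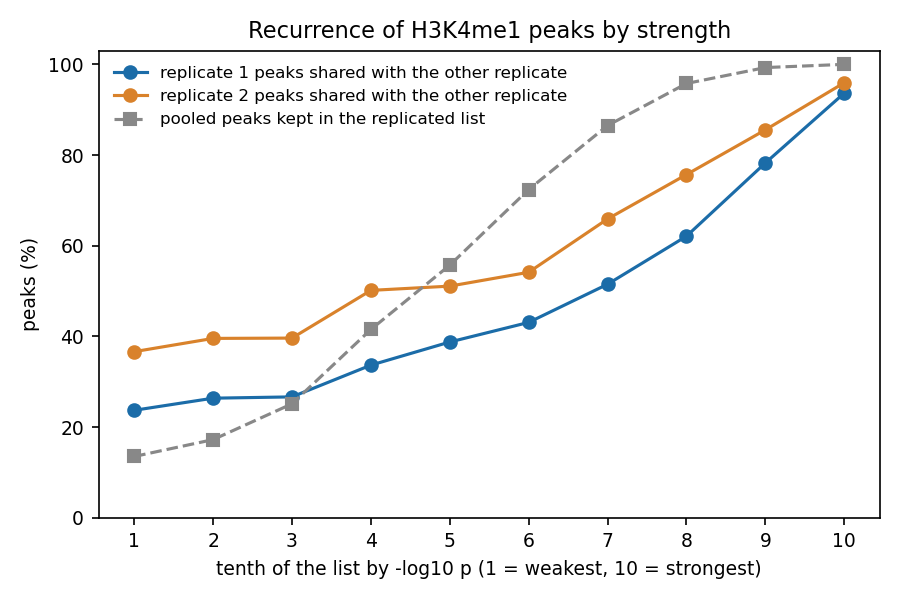
Share of peaks (%, vertical axis) in 10 equal bins of the list by −log10 p (horizontal axis, 10 = strongest), for peaks of each replicate shared with the other and for pooled peaks kept in the replicated list. In the weakest bin the shares are 23.7%, 36.6% and 13.5%, and in the strongest 93.7%, 95.9% and 100%.

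Between the replicates, oligodendrocyte lineage and housekeeping genes had more covered bases in replicate 1, and GABAergic lineage genes slightly more in replicate 2. For this comparison of 2 libraries, not of conditions, both lists were kept to the same number of strongest peaks. The median difference (replicate 1 minus replicate 2) was 1.11 percentage points for the oligodendrocyte list (percentile 99.9; 7 of 10 genes higher in replicate 1, with Mbp 2.76 and Sox8 2.63 points higher) and 0.723 points for the housekeeping list (percentile 98.1; 15 of 18 genes, with Polr2a 2.90 points higher). These 3 genes, and those named next, were chosen after their differences were seen. It was -0.19 points for the GABAergic list (percentile 1.74; 8 of 14 genes higher in replicate 2), where Slc32a1 had -1.74 points and Ascl1 2.49 points. The olfactory receptor list had a median difference of 0 against 0.199 points in random lists (percentile 0). Of its 1134 members 125 were higher in replicate 1 and 79 in replicate 2, and the rest did not differ. Its median was thus held at 0, and the percentile reflects only the offset of the random lists. The other 20 lists lay within the central 95%, among them midbrain patterning (0.221 points, percentile 81.5), dopaminergic lineage (-0.141 points, percentile 2.91), endothelial (percentile 3.89), microglia (percentile 57.7), erythroid (percentile 66.5) and mesenchyme (percentile 3.83). About 1.2 of 24 lists would lie outside by chance. The direction for the GABAergic list turned with the lists as deposited (percentile 94.0) and within 100 kb of the start site (65.6), and the oligodendrocyte list returned to the central 95% within 10 kb (65.6) and at equal covered length (95.5). Housekeeping genes returned to it with the lists as deposited (93.3). Other lists left the central 95% under some settings. More lay in replicate 2 for the serotonergic (2.22) and forebrain lists (1.5) within 10 kb. The same held for the serotonergic (0.57), mesenchyme (0.27) and dopaminergic lists (0.68) at equal covered length. With the lists as deposited, which hold more peaks in replicate 1, the midbrain patterning, pan-neuronal and glutamatergic lists had more in replicate 1. The pan-neuronal list also did so within 100 kb, and the vomeronasal receptor list lay below under both of these settings.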

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

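The alternatives that keep autosomal genes only, match random lists on CpG class as well, or thin list members to 100 kb apart were chosen after seeing the data, and the others before the data were examined. Over all results, 420 alternative values stayed on their side of the threshold or within the spread, 55 moved, 21 were stronger, 21 weaker and 4 reversed; the causes were not tested except where stated. No paired analysis was possible because there is only 1 group. Depth is unknown, so what it limits could not be measured.

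The mean number of peaks per replicate was 33649 with the top 25% of each list, by construction. The shared part of replicate 1 and replicate 2 was 56.0% and 68.4% with any shared base, 29.4% and 35.7% with 50% of both peaks, 50.9% and 57.2% with a −log10 q of at least 2, 48.4% and 59.8% with the top 25%, and 52.8% and 55.0% with the same number of peaks. The replicated share of pooled peaks was 51.7% when a peak in each replicate had to overlap by 50% of either length, 53.6% by 1 bp, and 67.8% with a −log10 q of at least 2. The rho of the signal was 0.448 with 50% of both peaks and 0.263 with the top 25%.

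The promoter ratio was 6.12 within 2.5 kb, 4.07 with start sites of all genes, 6.69 over bases, 6.47 in the pooled list and 5.95 to 6.30 with either replicate left out. The ratio of the mean flank maximum to the start site was 11.8 with observed to expected CpG of at least 0.75. The ratio of the autosomal median to the X chromosome was 11.8 for peaks per Mb, 13.4 in the pooled list and 12.6 to 13.3 with either replicate left out.

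Of gene lists, 6 stood above, but 2 with the top 25%; 4 stood below, but 2 when matched on gene length and 2 when thinned. Calls were also gained: 7 lists stood above within 10 kb, in the pooled list and in replicate 2 alone, and 8 in replicate 1 alone. Percentiles newly outside the central 95% were 99.8 (GABAergic), 99.7 (glutamatergic) and 99.4 (forebrain) within 10 kb, 97.7 for the glutamatergic list within 100 kb and 98.5 in the pooled list, and 97.7 for the forebrain list by number of peaks. The others were 98.1 and 97.9 for the GABAergic list in replicate 2 and replicate 1 alone, 99.1 for the glutamatergic list in replicate 1 alone, 1.42 for the erythroid list in replicate 2 alone, and 98.4 for the heart and skeletal muscle list matched on CpG class. Percentiles back inside the central 95% were, for the serotonergic and isthmic list, 91.7 within 10 kb, 93.1 within 100 kb, 95.4 by number of peaks, 92.1 matched on gene length, 91.0 with the top 25% and 96.3 matched on CpG class. They were 60.2 for neural progenitors with the top 25%. For the oligodendrocyte list they were 80.1 within 10 kb, 97.3 matched on gene length and 50.1 with the top 25%. For the Hox clusters they were 7.92 matched on gene length and 3.39 thinned to 6 genes, and for all Hox genes 4.58 and 3.15. For housekeeping genes they were 97.0 with the top 25%, 95.9 on autosomes and 94.0 matched on CpG class.

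Between replicates, 2 lists stood above the central 95% of random lists (higher in replicate 1), but 4 with the lists as deposited, 1 at equal covered length and 1 within 10 kb. Below it stood 2, but 4 at equal covered length. The olfactory receptor list was 1 of the 2, although its median difference was 0, with 125 members higher in replicate 1 and 79 in replicate 2. The GABAergic list reversed to percentile 94.0 with the lists as deposited and 65.6 within 100 kb, and the glutamatergic list to 99.8 with the lists as deposited. The oligodendrocyte list was at 95.5 at equal covered length and 65.6 within 10 kb, and housekeeping at 93.3 with the lists as deposited. The olfactory receptor list, whose median difference is 0, was at 30.0 at equal covered length and 50 within 10 kb, where the median of random lists was also 0. Lists newly outside were midbrain patterning (100), pan-neuronal (99.7) and vomeronasal receptor genes (0) with the lists as deposited, dopaminergic (0.68), serotonergic (0.57) and mesenchyme genes (0.27) at equal covered length, serotonergic (2.22) and forebrain genes (1.5) within 10 kb, and pan-neuronal (97.9) and vomeronasal receptor genes (0.33) within 100 kb.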

Other observations

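The test on the number of genes on the X chromosome was chosen after its result was in view, and the median signals of X and autosomal peaks had been seen before the test on signal was written. The gene families below were chosen after the results of the report had been seen, values of some of their members among them. The medians of the families were computed only afterwards.

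Groucho-type co-repressor, ephrin receptor and semaphorin genes were among the families with high H3K4me1 around them, and clustered adhesion genes and defensins had little. Of 20 families 11 lay above the central 95% of matched random lists and 3 below. Members such as Tle3 and Ephb2 already stood among the highest genes or widest peaks when the families were chosen. No chance expectation therefore applies to these counts. The 5 Groucho-type co-repressor genes (Tle) had a median of 16.4% (15.96% ± 0.55), with Tle3 at 36.5% and Tle6 at 19.6%. The 14 ephrin receptor genes had 9.70% (8.61% ± 1.05), with Ephb2 at 31.6% and Epha4 at 22.4%, and the 20 semaphorin genes had 7.97% (7.28% ± 0.20), with Sema6a at 26.8% and Sema3f at 25.3%. The other families above were Iroquois (8.56%), nuclear factor I (8.11%), Sox (6.34%), ribosomal protein (5.86%), Lhx (5.46%), Pou (5.21%), glutamate receptor (3.83%) and potassium channel genes (3.13%). Fox (percentile 90.4), Tbx (72.5), Kdm (95.6), Gabr (16.025), Zfp (38.8) and Hist1 genes (93.7) lay within the central 95%.

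Of 54 clustered protocadherin genes, adhesion genes expressed in neurons, 39 had no replicated peak within 50 kb, and the median was 0 against 6.05% in random lists. Pcdhgc3, Pcdhgc4 and Pcdhgc5, at the end of the cluster on chromosome 18, had 29.1% each. Beta-defensin genes had a median of 0 against 3.80%, with 30 of 42 without a peak. Keratin genes had 1.91% against 3.72% (percentile 0.79), but lay at percentile 47.8 when random lists were also matched on CpG class, a setting under which the protocadherin and defensin families stayed below and 11 families stood above. Members of these families share windows, so the number of independent regions is smaller than that of genes.

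The scarcity of peaks on the X chromosome was weighed first. Autosomal 1-Mb bins with like numbers of start sites had 15.5 times the covered share of X bins, while the same ratio for single autosomes ran from 0.717 to 1.26, which argues against fewer genes as the cause, and the ratio was 13.3 over bases outside repeats, which argues against repeats. In the top 10% of pooled peaks by signal (17 X peaks) the ratio of autosomal to X peaks per Mb was 55.2. In the lowest 50% (562 X peaks) it was 7.97, so it rose with signal by 6.93 times (95% counting interval 4.53 to 12.6). A lower signal on the X chromosome that puts peaks under the calling threshold would give such a rise. The test sorts called peaks by signal, however, so any other shortage of strong X peaks would give it too. It therefore cannot single out that explanation. The median signal of called peaks differed little (3.06 on the X chromosome and 3.11 on autosomes in the pooled list). Why the signal would be lower is open. The loss reached promoters, since 13.7% of 227 CpG-rich X start sites had a peak 1.1 kb downstream against 52.5% of 9497 autosomal ones. Male cells with 1 X chromosome and the inactive X chromosome of females may contribute, as may a step of the authors' processing, and no biological explanation was tested because both pools hold both sexes.

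The downstream flank of CpG-rich start sites was covered 1.72 times as often as the upstream flank (1.64 and 1.76 in the replicates). In 1191 CpG-rich genes with a single annotated transcript start the ratio was still 1.56, which argues against start sites annotated too far upstream as the whole cause. At 1860 sites with a start site of another gene on the other strand within 1 kb upstream, the ratio was 1.21 against 1.73 at the other 7865 sites, because the upstream maximum was higher (47.8% against 29.1%). The hypothesis that the weaker flank is the side without a transcription unit stays open, since 1.21 lies just between the bounds of 1.2 and 1.4 set for it. The upstream side of such a site is also the downstream side of its partner. Any cause tied to a gene's direction would therefore lower the ratio, so the test cannot single out this hypothesis. No biological explanation could be set against it by the design, which has 1 group.

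The unequal coverage of gene lists in the replicates was weighed last. At equal covered length 2 of the 3 lists (housekeeping at percentile 99.5 and GABAergic at 0.62) still lay outside the central 95%, which argues against unequal peak lengths as the whole cause. Of 8 lists of other brain regions or cell types, 2 lay outside at equal covered length, the serotonergic and isthmic list (percentile 0.57, 8 of 10 genes higher in replicate 2) and the mesenchyme list (0.27, 8 of 14), so a different share of such tissue in the pools may play a part. The rule set beforehand needed only a single list outside, which chance can meet, so the support is weak. The result also depends on the setting: at equal numbers of peaks none of the 8 lay outside within 50 kb or 100 kb, and 2 did within 10 kb (forebrain at 1.5 and serotonergic at 2.22). The midbrain's own dopaminergic list (0.68) moved the same way, so the shift was not limited to lists of other tissue. Gata2, Lmx1b and Zic1 of the serotonergic and mesenchyme lists also belong to midbrain or progenitor lists. Whether this speaks for or against a different share of tissue cannot be told here.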
